A study of Homo sapiens with 2 samples.

How the data were processed

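Huh-7 cells, a human hepatocellular carcinoma line, were grown without treatment, and total RNA was depleted of ribosomal RNA, fragmented and incubated with an antibody against m6A, per the labels' protocols. Strand-marked libraries (second strand labelled with dUTP) were read in pairs on an Illumina NovaSeq. The labels name 1 IP library and 1 input library. The protocol text also speaks of adipose RNA, but the titles of both samples name Huh-7, and that name is used here. The design compares IP with input in 1 cell line and holds no treatment.

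The submitters' processing notes list fastp, FastQC, HISAT2, HOMER, StringTie and edgeR, without roles. Which of them called peaks or levels, their settings and the genome build are not given in the sources used here. The authors' peak table, per the file headers, gives each peak a log2 fold of IP over input, a p-value and an adjusted p-value, a position, a gene and a region. All folds were above 1, the largest p was 0.0500 and 2462 peaks had an adjusted p of 0.05 or more, up to 0.0635, so the list was limited on the unadjusted p. The ratio of adjusted to unadjusted p implied that 63146 regions were tested. How the authors scaled the IP against the input library is not given in the sources used here, so a fold of 1 has no independent reference. The peak length, per the file headers, equalled the end minus the start plus 1, so coordinates count from 1. The deposited gene table, per the file headers, gives the FPKM of the input library for 25105 genes, all above 0. The FPKM went down to 1.78e-07, so whole reads could not be recovered from it, and no read depth can be given. Gene spans of 19112 genes matched by symbol overlapped those of GRCh38.p14 in 99.9% of cases, and coordinates are printed as the files give them.

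Peaks were joined to genes by Ensembl gene ID. The biotype came from the RefSeq table of GRCh38.p14 by symbol or synonym, which covered 80.7% of genes, with the 13 mitochondrial mRNAs set to protein-coding. A gene was called expressed at 1 FPKM or more in the input. Shares carry exact (Clopper-Pearson) 95% intervals. The design fixed before the data were examined called for a gene-level ratio of IP to input, but no IP level is used here, so that ratio, its pseudocounts and scalings were not computed. Each gene was instead given the log2 fold of its strongest peak, a measure chosen after the columns of the files were seen. For each gene list with 5 or more members with a peak, the median of that measure, and separately the share of members with a peak, was ranked among 10000 random lists of the same size, drawn from other protein-coding genes within 20 bins of input level (5 bins and non-coding genes for the long non-coding RNA list). A list was called above or below when it lay outside the central 95% of random lists. No p-value was computed across genes. A standard error of each peak's log2 fold, for lower 99% limits, was taken as that log2 fold divided by the normal deviate of its p, which takes the p as that of a normal test of the fold against 1.

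The 26 lists were fixed before the data were examined. They covered m6A writers, m6A erasers and readers, hepatocyte genes, oncofetal genes, cholesterol and fatty acid synthesis, bile acid and lipid export, glycolysis, cytosolic ribosomal proteins, replication-dependent histones, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation, proteasome, ZNF genes, immediate early genes, Wnt and Hippo genes, cell cycle, epithelial to mesenchymal transition, innate immune sensing, ferroptosis, autophagy, chromatin regulators, long non-coding RNAs, and 4 lists of markers of other cell types, which were too short to rank at 1 FPKM or more. The genes named are the 10 coding genes with the highest peak fold at 5 FPKM or more, the 10 with the most peaks, the 10 with the highest input level, the 2 highest and 2 lowest members of each list by strongest peak at 1 FPKM or more, and all expressed members of the 2 m6A lists. A few genes that this rule or the marker lists would name are not reported here. The planned rule ranked list members by the gene-level ratio, which the strongest peak replaces here. The 10 highest coding genes by level, the ranking by peaks of adjusted p under 1e-06, genes named for having no peak or no level, the pairs of opposite-strand peaks and the markers of other cell types named singly were chosen after their values were seen.

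The ranking was tested on simulated shifts in the strongest-peak fold. Each of 10555 genes was given a fold that fell with its level plus independent normal noise, and list members were drawn at random toward high levels. Real folds are maxima over several peaks, some genes have none, and real lists hold related genes, so the rates may differ for them. With no shift 5.50% of lists of 10 genes and 8.00% of lists of 30 fell outside the range, with a log2 shift of 0.5 these were 25.5% and 54.0%, and with a shift of 1.0 they were 74.0% and 99.0%. Alternatives were a stricter peak limit (adjusted p under 0.001), fold minimums of 2 and 4, other level minimums, merged overlapping peaks, other bins, matching on genomic span or on the number of peaks, the median peak of each gene, and peaks that overlap none on the other strand. No genome sequence or exon annotation was used here, so the planned DRACH motif search, the location of peak midpoints on transcripts and matching on exonic length were not run. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.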

Results

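N6-methyladenosine (m6A), a methyl mark on adenosines inside mRNA, was mapped in untreated Huh-7 cells, an established line from a human hepatocellular carcinoma. RNA depleted of ribosomal RNA was fragmented, and 1 library was made from fragments pulled down with an antibody to m6A (the IP) and 1 from fragments taken before the pull-down (the input). The data asked where in the transcriptome IP reads exceeded input reads, and in which genes. The authors' peak list held 49746 regions with a fold of IP over input, and their gene table held the input level of 25105 genes in FPKM. With 1 library of each kind no value had a replicate check, and the FPKM values carry no read counts, so the depth of both libraries is unknown.

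The input library held the transcripts of liver cells at high levels. AFP, the fetal serum protein that many liver tumours make, was the most abundant protein-coding transcript at 2380 FPKM. FTL, the ferritin light chain, followed at 2200 FPKM, and ALB, which encodes serum albumin, at 1202 FPKM. GAPDH, EEF1A1, FTH1, AMBP, APOA1, ACTB and H2BC12 made up the rest of the 10 highest coding genes, between 616 and 861 FPKM. The 10 highest genes of any kind were small structural RNAs and related loci, led by RN7SL1, the RNA of the signal recognition particle, at 51026 FPKM, and 7 of these 10 had no peak. RN7SL2, RNU1-3, RN7SK, RMRP, RPPH1, FP671120, RN7SL4P, CR392039 and RNU1-4 were the others, down to 5556 FPKM. FP671120 and CR392039 each spanned 61 nt, less than the shortest listed peak (101 nt), so the lack of a peak there says little. Among markers of other cell types, the endothelial genes VWF, CDH5, KDR, TEK and CLDN5 were not listed, and PECAM1 stood at 1.33 FPKM. The leukocyte genes PTPRC, CD3E and MS4A1 were not listed either, whereas LYZ, which encodes lysozyme, stood at 83.8 FPKM. CD14 stood at 1.72 FPKM, CD68 at 0.950 and CSF1R at 0.0144. Of 8 fibroblast and stellate cell genes, PDGFRB (1.46 FPKM), COL3A1 (1.23) and COL1A2 (1.17) reached 1 FPKM, and COL1A1 stood at 0.159 FPKM. Of 6 bile duct genes, SOX9 (35.7 FPKM), EPCAM (12.9), KRT19 (11.7) and SPP1 (1.59) reached 1 FPKM.

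The peaks covered 15890 genes. The fold and p of each peak are the authors' own values and serve here only to describe and rank peaks within this list. The median peak was 2.14-fold over input (quartiles 1.66 and 3.32), 56.4% of peaks were at 2-fold or more and 19.7% at 4-fold or more. An adjusted p under 0.001 was given for 21959 peaks (44.1%), and 15649 peaks (31.5%) also reached 2-fold. A peak listed on the other strand overlapped 5983 of the peaks, counted from first to last base with any introns between. Among coding genes at 5 FPKM or more the highest log2 fold belonged to CBSL, at 8.81, in a coding exon on chromosome 21 from 6447613 to 6450935. NSF (7.56), TSFM (7.16), EIF3CL (7.03), RNF213 (7.02), PSMA5 (6.86), CACYBP (6.62), THBS1 (6.58), LACTB2 (6.47) and CLP1 (5.89) followed. NSF drives the fusion of vesicles with membranes, TSFM is a translation factor of mitochondria, and THBS1 encodes the matrix protein thrombospondin 1. CBSL and EIF3CL have near-identical copies elsewhere in the genome (CBS and EIF3C), so their levels and folds are uncertain. The CLP1 peak, from 57638123 to 57650715 on chromosome 11, began upstream of the listed gene start at 57648992. The gene it belongs to is therefore uncertain. Of peaks in genes with a listed level, 93.5% lay inside the span of their gene. The peaks of NSF, TSFM, RNF213, PSMA5, CACYBP, THBS1 and LACTB2 had adjusted p-values only between 0.000391 and 0.00246. Of genes ranked again with peaks of adjusted p under 1e-06 alone, a limit set after the values were seen, EIF3CL (6.31) and CLP1 (5.89) were followed by CHD3 (5.59), TCIM (5.18), GON4L (5.11), DAPK3 (5.03), IST1 (5.00), H4C8 (5.00), PKP4 (4.99) and EEF1D (4.98). The peak of DAPK3, a protein kinase linked to cell death, lay in the 3' UTR on chromosome 19 from 3958452 to 3959803.

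The 3' UTR held the most peaks. Of all peaks 49.2% lay there (exact binomial 95% interval 48.8 to 49.7%), against 20.7% in coding exons, 12.3% in 5' UTRs, 11.6% in exons of non-coding transcripts and 5.93% in introns, by the region the authors gave each peak. Among peaks of 2-fold or more with an adjusted p under 0.001 the 3' UTR share was 54.1% (53.4 to 54.9%), that of coding exons 14.8% and that of introns 2.35%. Along the genomic span of the gene, 33.7% of peak midpoints fell in the last 10% and 8.69% in the first 10%. Peaks in 5' UTRs fell in the first 10% in 42.8% of cases, and peaks in 3' UTRs in the last 10% in 57.0%. The median fold was 3.00 for non-coding exons, 2.32 for 5' UTRs, 2.17 for introns, 2.09 for 3' UTRs and 1.84 for coding exons. The intervals cover counting error only. A peak's length runs from its first to its last base across any introns between (median 601 nt, up to 741019 nt), so a peak can touch several regions while it is listed under 1.

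**Figure D1:**
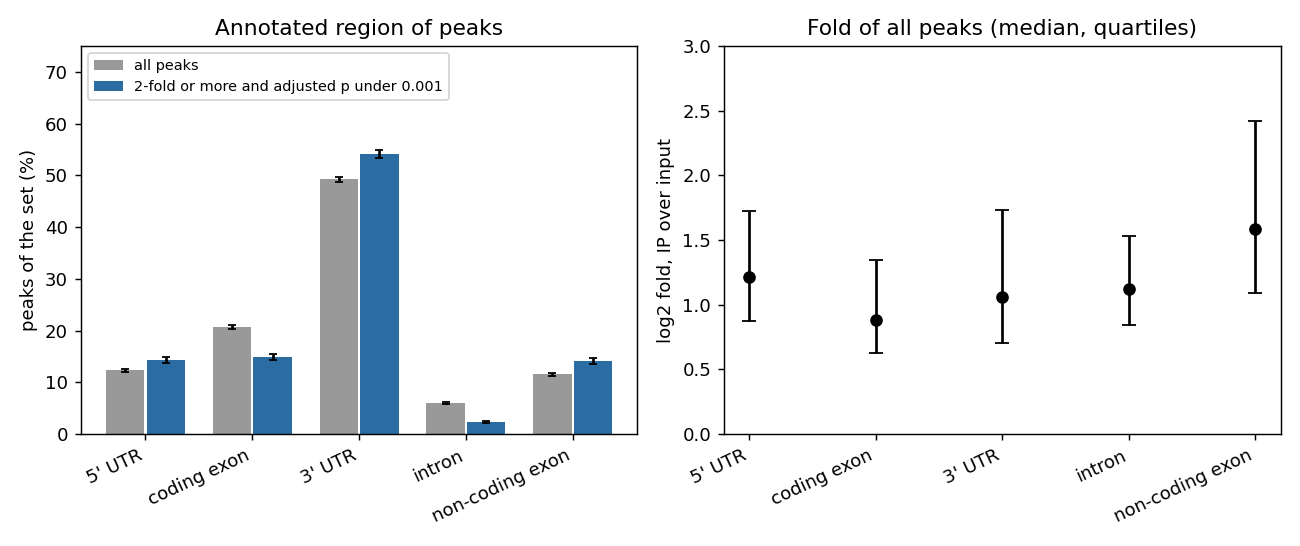
Left, share of peaks (%) in each region the authors annotated, for all 49746 peaks (grey) and for the 15649 of 2-fold or more with adjusted p under 0.001 (blue), with exact binomial 95% intervals. Right, median and quartiles of the log2 fold of IP over input of all peaks in each region; the 3' UTR held 49.2% and 54.1% of the peak sets, and non-coding exons had the highest median fold, 3.00 on the linear scale.

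Most expressed genes carried a peak. Of 13630 genes at 1 FPKM or more, 11188 (82.1%, 81.4 to 82.7%) had 1 or more, and of 10555 protein-coding genes at that level 10155 (96.2%, 95.8 to 96.6%) did. Long non-coding RNA genes had a peak in 75.1% of cases, genes of the biotype transcribed pseudogene in 62.7%, those of the biotype pseudogene in 24.3%, small nucleolar RNAs in 7.14% and microRNA genes in 0.971%. The shortest listed peak was 101 nt, and gene length was not matched across these classes. The low shares of short RNAs therefore do not show that the mark is absent. A coding gene had a median of 3 peaks, and 396 genes had 10 or more. TTN, which encodes the giant muscle protein titin, had 90 peaks at 4.22 FPKM, the most of any gene. Of these, 88 overlapped the span of its antisense gene TTN-AS1 at least in part. The long non-coding RNAs HELLPAR and KCNQ1OT1 had 59 each, and DST (34), MACF1 (29), ADGRV1 (27), RNF213 (24), CCDC88A (23), DYNC1H1 (23) and HNRNPU (22) followed. DST and MACF1 encode very large proteins that link parts of the cytoskeleton, and DYNC1H1 the heavy chain of the motor dynein. Over all genes listed, with no level minimum, 58.2% had a peak, and with an adjusted p under 0.001 the share at 1 FPKM or more was 68.6%.

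Strong peaks were more frequent in genes of low level. In the lowest decile of coding genes by input level (median 1.32 FPKM) 53.9% (50.8 to 56.9%) had a peak of 4-fold or more, against 15.2% (13.1 to 17.6%) in the highest decile (median 39.1 FPKM). The median log2 fold of a gene's strongest peak was 2.21 in the lowest decile and 1.09 in the highest. The share with any peak was 90.8% in the lowest decile, 98.3% in decile 7 and 92.7% in the highest. Genes with a peak had a median level of 5.63 FPKM and the 400 coding genes without one 3.81 FPKM, a log2 ratio of 0.56, but among genes at 5 FPKM or more the ratio was -0.77. These are shares across genes of 1 pair of libraries, and genes are not independent replicates.

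**Figure D2:**
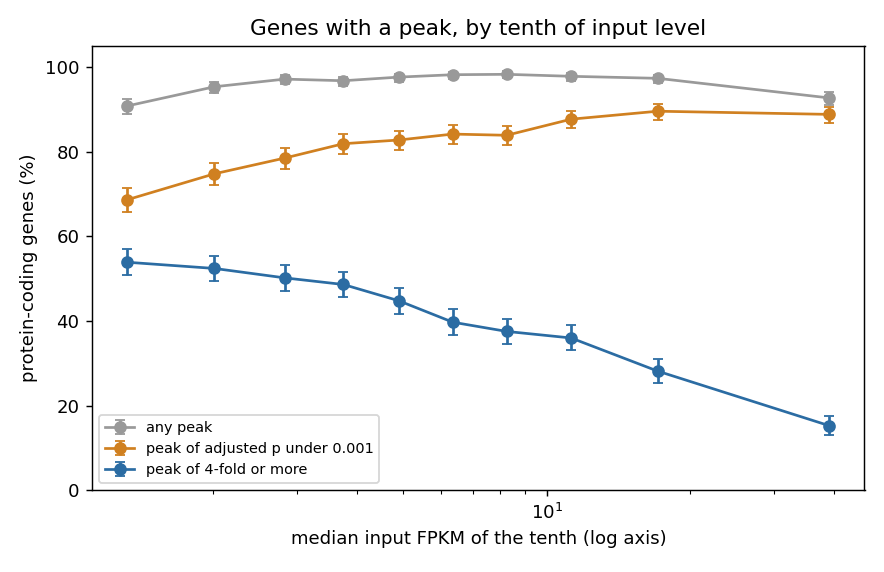
Share of protein-coding genes (%) with any peak (grey), a peak of adjusted p under 0.001 (orange) and a peak of 4-fold or more (blue), by decile of input level, against the median FPKM of each decile on a log axis, with exact binomial 95% intervals. The share with a 4-fold peak was 53.9% in the lowest decile and 15.2% in the highest.

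All 10 genes of the m6A writer list were expressed and had peaks. That share of 100% was also the median of random lists (percentile 58.1). PCIF1 methylates the adenosine next to the cap, and the others are enzymes and partners that place the mark. RBM15 had the strongest, at a log2 fold of 3.63, followed by ZC3H13 (3.50), WTAP (3.04), METTL16 (2.66), RBM15B (2.62), PCIF1 (2.59), VIRMA (2.40), METTL14 (2.35), CBLL1 (1.79) and METTL3 (1.55). METTL3, the catalytic subunit of the main methyltransferase, stood at 9.70 FPKM and its partner METTL14 at 2.61 FPKM. The strongest peak of 8 of the 10 was at 4-fold or more, a share of 80.0% against 40.0% in random lists (percentile 99.1). All had a peak of 2-fold with an adjusted p under 0.001, against 70.0% (percentile 98.3). Both measures were added after the values were seen. The list median of 2.61 lay at the edge of the range of 10000 random lists of the same size matched on input level (median 1.78, 95% range 1.17 to 2.60, percentile 97.6). With genes at 5 FPKM or more the percentile was 96.0 and with peaks of adjusted p under 0.001 it was 96.8, both inside the range. Matched also on the number of peaks per gene it was 97.4, also inside, and with each gene's median peak in place of its strongest the list lay at -0.054 from the random median.

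All 18 genes that remove or bind the mark also had peaks. The m6A readers YTHDF3 (3.28), IGF2BP3 (2.77), PRRC2A (2.51), YTHDF2 (2.38), YTHDF1 (2.29), IGF2BP1 (2.19), EIF3A (2.12), YTHDC1 (2.01), IGF2BP2 (1.96) and YTHDC2 (1.62) had the stronger peaks. RNA-binding proteins RBMX (1.11), HNRNPA2B1 (0.93), FMR1 (0.85), LRPPRC (0.55) and HNRNPC (0.51) had weaker ones, and ELAVL1 stood at 1.23. Of the demethylases, FTO had a log2 fold of 1.81 at 1.35 FPKM and ALKBH5 0.82 at 45.1 FPKM. The list median of 1.88 was within the random range (0.96 to 1.95, percentile 96.3) and above it among genes at 5 FPKM or more (percentile 98.5) and without peaks that overlap the other strand (98.2). The strongest peaks of WTAP, ALKBH5 and ELAVL1 overlapped a peak listed on the other strand, so the gene they belong to is uncertain.

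**Figure D3:**
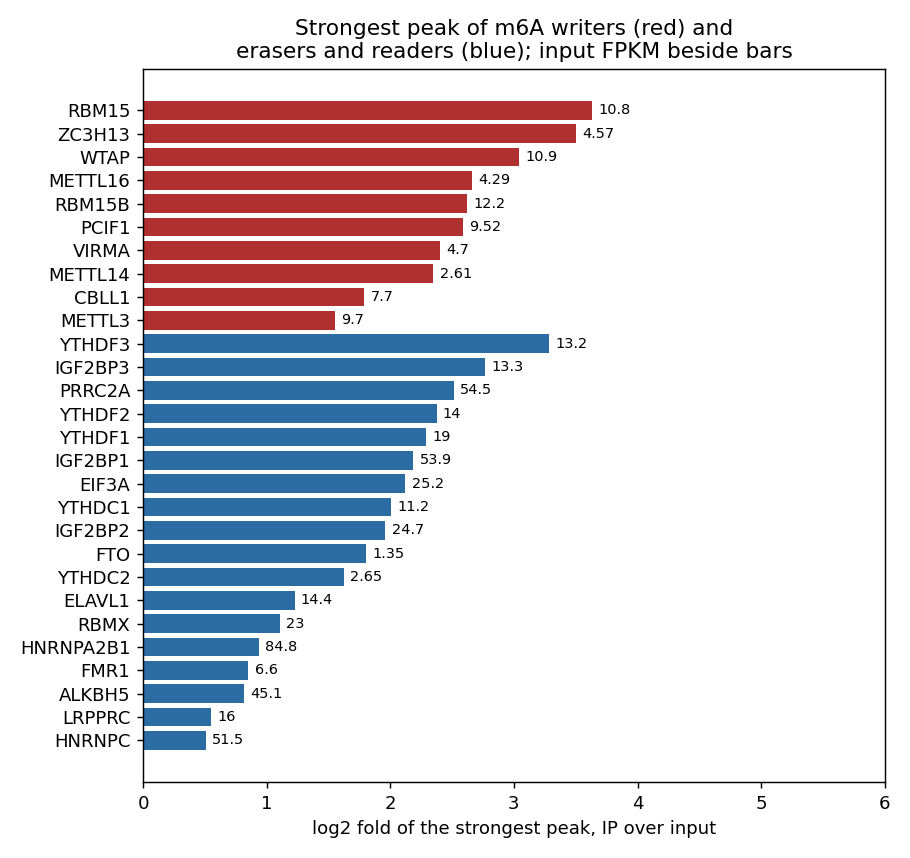
Log2 fold of IP over input of the strongest peak of each m6A writer (red) and each eraser or reader (blue), with the input level in FPKM beside each bar. RBM15 (3.63) and METTL3 (1.55) bound the writers, YTHDF3 (3.28) and HNRNPC (0.51) the other list.

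Liver genes spanned a wide range. In the hepatocyte list the transcription factors CEBPA and FOXA1 had the strongest peaks, with log2 folds of 4.64 and 4.27, while the plasma proteins RBP4, the carrier of retinol, and TTR, the carrier of thyroxine, had 0.29 and 0.44. APOC3, APOH and VTN, at 38.1 to 182 FPKM, had no peak. The median of the 23 hepatocyte genes, 1.07 over the 20 with a peak, was close to that of random lists (1.06, percentile 50.9), but 39.1% of the list had a 4-fold peak against 17.4% of random lists (95% range 4.35 to 30.4%, percentile 99.7). With peaks of 2-fold or more and an adjusted p under 0.001 the share was 43.5% against 39.1% (percentile 59.5), inside the range; both measures were added after the values were seen. Of 11 coding oncofetal genes, IGF2, the fetal growth factor, had 3.10 (adjusted p 0.000846) and PEG10 3.02, against 0.65 for AFP and 0.68 for LIN28B. SPINK1 had no peak, and the list median of 1.80 was within the range (percentile 95.6). In cholesterol and fatty acid synthesis, ACACA, the enzyme that makes malonyl-CoA, had 2.88 and HMGCS1 2.70, and SCD (0.44) and CYP51A1 (0.46) were lowest, with a list median of 1.19 (percentile 55.7). In bile acid and lipid export, NR0B2 (3.05) and the cholesterol exporter ABCA1 (2.63) were highest and CYP27A1 (0.53) and FGFR4 (1.10) lowest (median 1.47, percentile 33.0), and CYP7A1, CYP8B1 and SLC10A1 were not listed. In glycolysis PKM (3.24, adjusted p 0.000455) and PDK1 (2.46, adjusted p 0.00959) were highest, ENO1 (0.48) and TPI1 (0.52) lowest, and ALDOA, at 114 FPKM, had no peak (median 1.51, percentile 76.9). The strongest peaks of CEBPA and IGF2 overlapped a peak on the other strand.

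Several lists of regulatory genes had stronger peaks than random lists of the same level. Of 284 ZNF genes with a peak, which encode zinc finger proteins, the median log2 fold was 2.72, against 1.97 for random lists (95% range 1.83 to 2.14), no random list was as high, and 245 of 288 had a 4-fold peak. ZNF182 (5.39) and ZNF821 (4.54) were highest, ZNF395 (0.84) and ZNF414 (0.89) lowest. The 26 immediate early and short-lived regulators had a median of 2.55 against 1.60 (1.22 to 2.14, percentile 99.97), led by the transcription factor JUN (4.46) and the phosphatase DUSP1 (3.82), with ID1 (0.60) and ID3 (1.12) at the low end. The 25 Wnt and Hippo genes had a median of 2.57 against 1.72 (1.30 to 2.30, percentile 99.9), led by TEAD4 (3.78), the DNA-binding partner of YAP1, and the tumour suppressor APC (3.60), with LGR5 (0.99) and TCF7L2 (1.01) lowest. The 32 chromatin regulators had a median of 2.32 against 1.61 (1.26 to 2.09, percentile 99.7), led by TET3 (4.64), which oxidises methylcytosine, and ARID1B (3.93), with HDAC1 (0.91) and HDAC2 (1.27) lowest. Each percentile is a description of these libraries. At the rates found for simulated lists of 10 and 30 genes with no shift, between 1.21 and 1.76 of 22 lists would fall outside the 95% range. The simulated lists held unrelated genes with independent folds, so the rate for the real lists may differ. Matched on the number of peaks per gene as well as level, the chromatin list was inside the range (percentile 94.3), as were the chromatin and the Wnt and Hippo lists with median peaks (percentiles 86.3 and 89.5).

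Lists of nuclear oxidative phosphorylation genes, mitochondrially encoded mRNAs and proteasome genes had weaker peaks than random lists. The 40 nuclear genes of oxidative phosphorylation with a peak had a median log2 fold of 0.83 against 1.47 for random lists (1.18 to 1.90), and no random list was as low. COX5A and NDUFB4 were at 0.49, and SDHD (3.88, adjusted p 0.0101) and NDUFA9 (2.57, adjusted p 0.0063) were highest. ATP5F1B, a subunit of ATP synthase at 230 FPKM, and COX8A, at 197 FPKM, were among 6 of the 46 without a peak, a share with a peak of 87.0% (percentile 0.555, and 2.85, inside the range, when matched also on genomic span). Of 12 mitochondrially encoded mRNAs at 1 FPKM or more, 6 had a peak, with a median of 1.10 against 2.02 (1.25 to 2.96, percentile 0.480); MT-ND2 (1.40) and MT-ND6 (1.29) were highest, MT-ND4 (0.52) and MT-ND1 (0.54) lowest. This list was inside the range with median peaks (percentile 16.6) and when matched also on the number of peaks per gene (3.42). Its call also rests on the listed level of these mRNAs, a median of 3.10 FPKM, to which the random lists were matched. Coding genes of the highest decile of level had a median strongest peak of 1.09, close to that of this list. No match at a higher level was run. The 29 proteasome genes with a peak had a median of 0.99 against 1.32 (1.00 to 1.77, percentile 2.12), with PSMD3 and PSMB3 at 0.53 and PSMA5 (6.86) and PSMC1 (3.12) highest; the list was inside the range with 10 bins of level (percentile 2.87), when matched also on genomic span (2.84) and with median peaks (12.3). Of 31 proteasome genes, 93.5% had a peak against 96.8% in random lists (percentile 34.7), inside the range. A peak of 2-fold with an adjusted p under 0.001 was found in 29.0% against 54.8% (percentile 0.305). A 4-fold peak was found in 9.68% against 22.6% (percentile 2.07). The latter 2 measures were added after the values were seen. Replication-dependent histone genes had a peak in 76.0% of 25 members (percentile 2.24), a share inside the range under every alternative (percentiles 7.00 to 35.4), and the median of those with one, 0.89, was within the range (percentile 25.9). H4C8 (5.00) and H2BC8 (2.54) were highest, H4C3 (0.38) and H3C7 (0.40) lowest, and histone genes share near-identical sequences that reads cannot always separate. Cytosolic ribosomal protein genes had a median of 1.00 (percentile 21.2), from 0.30 for RPLP2 to 3.22 for RPS24 and 3.48 for RPS29, with RPL17, RPLP0, RPLP1, RPS16 and RPS27 without a peak. Their share with a peak was within the range (percentile 75.5). By measures added after the values were seen, 6.76% had a 4-fold peak against 16.2% of random lists (percentile 0.550). A peak of 2-fold with an adjusted p under 0.001 was found in 29.7% against 41.9% (percentile 1.05).

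The other lists lay within the random ranges of strongest peaks matched on level. In the cell cycle list (median 1.31, percentile 31.7) the transcription factors E2F2 (3.85) and E2F3 (3.13) were highest, the mitotic genes CDC20 (0.48) and BUB1 (0.52) lowest, and CCNB2 had no peak. In epithelial to mesenchymal transition (median 1.65, percentile 63.1) SMAD2 (6.58, adjusted p 0.00211) and SMAD7 (3.10) stood above ITGB1 (0.71) and FN1 (0.75). In innate immune sensing (median 1.74, percentile 41.3) the interferon receptor chains IFNAR2 (4.49) and IFNAR1 (2.48) stood above STAT2 (1.05), and DHX58 was not listed. In ferroptosis and oxidative stress (median 0.91, percentile 5.19) the stress sensor KEAP1 (2.24) and its partner NFE2L2 (2.15) stood above FTL (0.34) and HMOX1 (0.62). The NFE2L2 peak had an adjusted p of only 0.0210. In autophagy (median 1.58, percentile 27.9) ATG2A (3.03) and WIPI2 (2.98) stood above GABARAPL1 (0.79) and ATG9A (0.85). Among 13 long non-coding RNAs (median 1.83, percentile 66.8) KCNQ1OT1 (4.79, adjusted p 0.00164) and FTX (3.69) stood above GAS5 and SNHG1 (both 0.68), and OIP5-AS1 and SNHG3 had no peak. Outside the range in an alternative were the long non-coding RNAs with median peaks (0.74 against 1.21, percentile 0.0300), the ferroptosis list matched on the number of peaks (percentile 1.35), and the innate list by its share with a 2-fold peak of adjusted p under 0.001 (88.9% against 66.7%, percentile 97.7). The strongest peaks of ZNF821, IFNAR2, PSMC1, KCNQ1OT1, FTX, CLP1 and APOA1 overlapped a peak on the other strand.

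**Figure D4:**
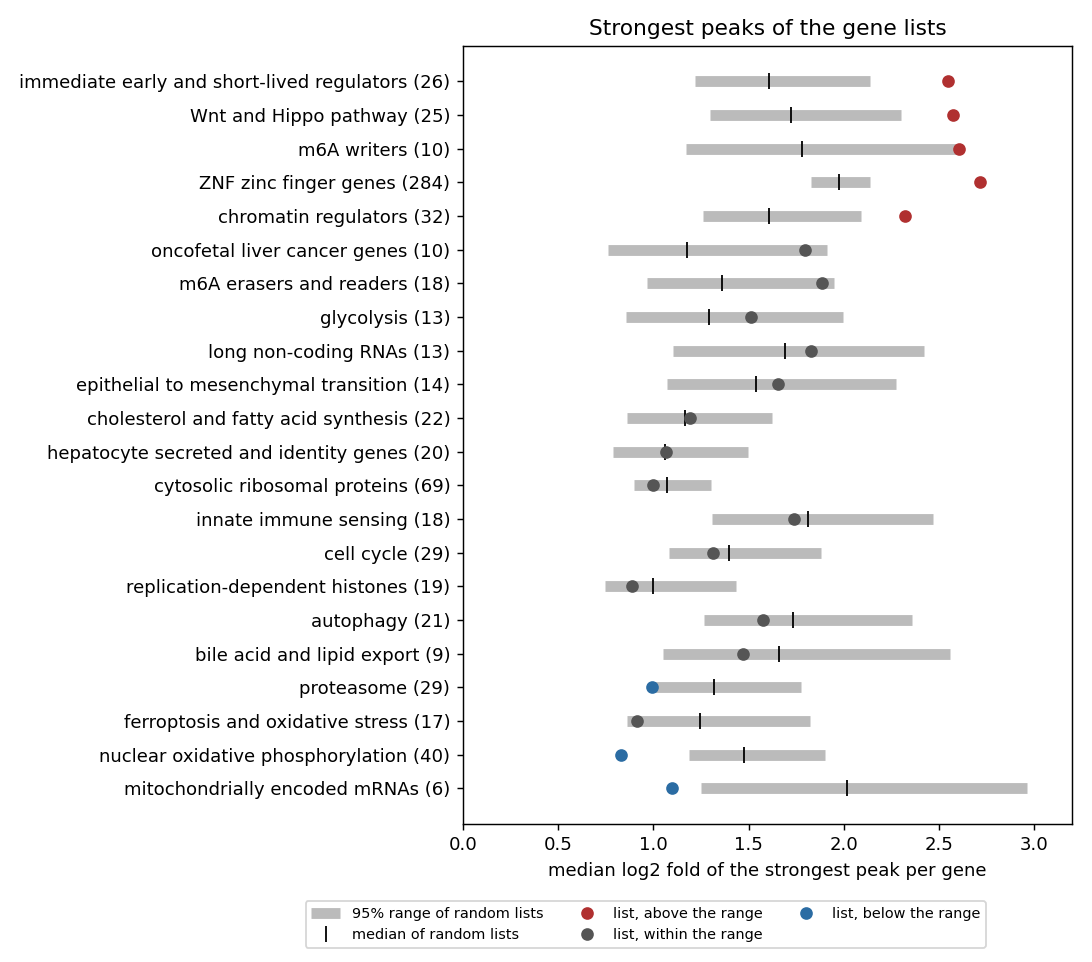
Median log2 fold of the strongest peak per gene for each of 22 gene lists (dots, members with a peak in brackets), with the median (tick) and 95% range (grey bar) of 10000 random lists matched on input level. Zinc finger genes (2.72) lay above their range and nuclear oxidative phosphorylation genes (0.83) below theirs.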

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

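All tests of the input level trend and of opposite strands, and the match on the number of peaks, were chosen after the results were seen. Signals outside the comparisons were these. A total of 1600 peaks lay in 1273 genes with no level in the gene table, with a median log2 fold of 1.56, and 76 peaks had no gene. On the mitochondrial genome 8 peaks were listed, in MT-ND1, MT-ND2, MT-CO3, MT-ND4, MT-ND5 and MT-ND6, with log2 folds from 0.52 to 1.40.

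Of 22 lists, 5 had stronger and 3 weaker strongest peaks than random lists of the same input level. Genomic span is argued against as the whole cause, since 7 of the 8 lists stayed outside the range on the same side when matched on it. That span counts introns, and exonic length was not matched, so the length of the mRNA stays open. Weak peaks near the p limit are argued against likewise, since 6 of 8 lists stayed outside with peaks of adjusted p under 0.001. The mitochondrial list had too few such peaks to rank, and the m6A writers lay inside at percentile 96.8. More chances of a strong peak in genes with more peaks are argued against as the whole cause only by a match chosen after the results were seen. That match, on the number of peaks, left a median of 0.876 of the 8 lists' differences from random lists and kept 5 of 8 outside. The call ended for the m6A writers, which already lay at the edge (difference 0.83 before and 0.71 after, percentile 97.6 and 97.4), and for the chromatin regulators (0.71 and 0.40, percentile 99.7 and 94.3) and mitochondrial mRNAs (-0.92 and -0.63, percentile 0.480 and 3.42), whose differences shrank, so a part from the number of peaks per gene stays open there. The test set beforehand gave each gene its median peak and kept 3 of 8 lists outside. By its preset limits that is too many to name the number of peaks as the cause and too few to argue against it. A median over mostly weak peaks also hides a single strong site, so that test leaves the question undecided. No biological explanation was tested, since the design has no contrast beyond IP against input.

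The strongest peak was weaker in genes of higher input level. A p limit that hides weak peaks of low genes cannot add strong ones, yet the share of genes with a 4-fold peak was 3.53 times as high in the lowest decile of level as in the highest (3.06 to 4.16). Counting noise that inflates folds of low genes is argued against as the whole cause by the same ratio over peaks whose lower 99% limit, from the standard error that each p implies under a normal approximation, was still 4-fold, 2.19 (1.81 to 2.72), but that share was 23.5% in the lowest decile, 30.6% in decile 3, 25.5% in decile 8 and 10.7% in the highest, so a part from noise among the lower deciles stays open. Shorter genomic spans among abundant transcripts are argued against as the whole cause by 5 of 5 quintiles of span. In each, the lower-level genes had the higher share with a 4-fold peak of adjusted p under 1e-06 (ratios 1.22 to 1.74). Exonic length was not matched, so a part from it stays open. The input level also stands in the denominator of the fold, and the antibody may saturate on abundant transcripts; both stay open, and no biological explanation was tested.

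Peaks of genes on opposite strands lay at the same place with like folds. Of all peaks 5983 overlapped a peak on the other strand, and 61 of the 90 TTN peaks did. Overlap was counted from first to last base, any introns included, so the exonic parts of such peaks need not meet. In 610 pairs that shared 50% or more of the longer peak, the log2 folds differed by a median of 0.20, against 0.83 (0.76 to 0.91) in shuffled pairs. An example is the pair in the 3' UTRs of PRSS23 (3.30) and the Wnt receptor FZD4 (3.03) on chromosome 11, from 86950375 to 86952591 and 86950303 to 86952428, and another ABI2 (2.58) and RAPH1 (2.53) on chromosome 2. This is consistent with reads counted without regard to strand, although the libraries mark it, and which gene of such a pair carries the mark then stays open.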

How the results depend on the processing

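Alternatives not listed among those planned (fold minimums of 2 and 4 beyond the peak count, coding genes alone, span and peak-number matches, median peaks, strict peaks for folds, opposite-strand peaks) were chosen after seeing the data. Of these, the tests of list folds by span match, median peaks and strict peaks had their expected outcomes set before their results were seen. With an adjusted p under 0.001 the peaks numbered 21959, with a median log2 fold of 1.55 (1.10 for all), a 3' UTR share of 54.2% and a gene share of 68.6%. At 2-fold or more 28074 peaks were left, 47.1% in 3' UTRs, and 54.1% with both limits. Without peaks that overlap the other strand the 3' UTR share was 50.1% and the gene share 78.8%. The gene share was 91.6% at 5 FPKM or more, 58.2% with no minimum and 96.2% for coding genes. Lists with stronger peaks than random numbered 5 as reported, 2 with median peaks and 3 matched on the number of peaks. Lists with a higher share of genes with a peak numbered 1 as reported, 3 with an adjusted p under 0.001, 0 at 5 FPKM or more, and 6 with peaks of 4-fold, of 2-fold with that p, or of the latter matched on span. Lists with a lower share numbered 3 as reported, 1 at 5 FPKM or more or matched on span, and 4 with peaks of 4-fold, of 2-fold with that p, or of the latter matched on span. Peaks of 4-fold or more and a 5 FPKM minimum reversed the log2 ratio of levels with against without a peak from 0.56 to -0.69 and -0.77. The m6A writers lay at -0.054 from the random median with median peaks, and the ZNF share at -1.67 percentage points at 5 FPKM. The cause of these was not tested. Of 324 comparisons of single lists, regions and levels with an alternative, these 4 reversals included, 260 kept their call or value. Lists that were within the range and stayed there count among these, so the total says little about the lists called outside. Of the 8 lists called outside for fold, 3 stayed outside on the same side with median peaks. Not run were the gene-level ratio with its pseudocounts and scalings, DRACH and its variants, midpoint and overlap locations, canonical transcripts and exonic length. No paired analysis was possible because each group has 1 library. Read depth is unknown, so what depth limits cannot be stated beyond the p of each peak.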

Other observations

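The test on muscle genes was set before their levels were seen, and the counts over TTN-AS1 and nuclear copies were chosen after. Some genes with a strong peak were also highly expressed: CEBPA stood at 140 FPKM with a log2 fold of 4.64, PEG10 at 319 FPKM with 3.02, IGF2 at 412 FPKM with 3.10 and APOB, the structural protein of secreted lipoproteins, at 502 FPKM with 2.37, against a median of 1.09 in the highest decile of coding genes. FGA and TF, which encode a fibrinogen chain and transferrin, had 2.31 and 2.97, whereas FGB, another fibrinogen chain, had 0.77. The non-coding RNAs NORAD (2.38), LINC00261 (2.81) and MALAT1 (1.59, at 360 FPKM) carried peaks, and the RNA-editing enzyme ADAR had 2.06 at 40.2 FPKM. The IGF2 and MALAT1 peaks had adjusted p-values of 0.000846 and 0.000306, against 0 as listed for CEBPA, PEG10 and APOB, so they are less well supported. The strongest peaks of CEBPA, IGF2 and MALAT1 overlapped a peak on the other strand, so the gene they belong to is uncertain. These genes were chosen after their values were seen.

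Mitochondrial mRNAs were listed at lower levels than the nuclear genes of the same complexes. The 13 ranged from 0.709 to 11.6 FPKM with a median of 2.97, against 14.0 for nuclear oxidative phosphorylation genes, a factor of 4.71. Adding all fragments of the 50 nuclear copies listed would raise the mitochondrial total 1.32-fold, short of that factor. The cause of the gap was not tested. The mapping settings are not given, so whether these levels reflect the abundance of the mRNAs stays open.

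TTN held more peaks than any other gene, 90, of which 27 had an adjusted p under 0.001 and 37 reached 2-fold. A muscle programme in the culture was a candidate explanation, but only 1 of 14 sarcomere genes of a list set beforehand reached 1 FPKM (NEB, 1.47 FPKM), and DES stood at 0.109, ACTN2 at 0.0156 and MYH6 at 0.00402, which argues against it. Of the TTN peaks, 88 overlapped the span of TTN-AS1 at least in part, itself a gene at 0.666 FPKM, and 61 overlapped a peak on the other strand.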
